A study of Homo sapiens with 6 samples.

How the data were processed

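Poly(A) RNA of cultured primary human keratinocytes was sequenced on a BGISEQ-500 instrument, per the labels' protocols, from 3 progenitor and 3 differentiated cultures. Differentiation was induced at 100% confluence with 1.2 mM calcium for 96 hours, per the labels. The deposited files hold whole-number counts of reads per gene row, named by gene symbol, 47352 rows in each of 6 files, not normalized. The submitters' processing notes name STAR, bedtools, DESeq and the builds hg19 and GRCh37, without versions or roles; the annotation release, strand setting and counting rule are not given in the sources used here. Because the files use that build and the reference at hand is GRCh38, no coordinates are given. RefSeq names of assembly GRCh38.p14 served only to look up symbols and gene type, and GENCODE release 29 transcripts only to obtain lengths and GC content.

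How the counts were made affects what they can show. Low counts fall on multiples of 3 more often than on their neighbours: on average over libraries 1534 rows hold a count of 3, against 827 with 2 and 412 with 4, and 663 hold 6 against 395 with 5 and 264 with 7. How reads became counts was not settled, so a count may not be 1 independent read; intervals and floors based on counts cover counting error only and would be too narrow where a read was counted more than once. Rows that overlap or are near copies of each other can share reads, as strand use is not stated, so genes of multigene families such as the SPRR, LCE and KRT6 genes are uncertain as single genes. For no named gene did another row lie within 5% of its counts in all 6 libraries.

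Libraries were grouped by their labels. Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group (minimum count 10, minimum total 15), glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment over 22390 tested rows and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Levels are CPM on TMM-adjusted library sizes, with SD over 3 libraries. A library at 0 counts was given 3 counts for a bound, which is 0.0149 to 0.0160 CPM here, and ratios with 1 to 3 counts carry an exact 95% interval. Lists were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01, adjusted over 30 lists. Of 826 list members 8 were found under an older or newer symbol fixed beforehand and 2 under a RefSeq synonym, and 1, LSM8, was not matched.

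The replicate numbers pair the libraries: the labels give both states the same numbers and culture names, and deviations from the group means correlated at 0.454, 0.469 and 0.332 across genes for equal numbers. For unequal numbers the values were -0.321 to -0.0658. Deviations within a group sum to 0 for each gene, so positive values for equal numbers force negative ones on average for unequal numbers. The latter therefore add no further support. A fit with the replicate number as a block is one of the alternatives.

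The main design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names 9 markers (KRT5, KRT14, KRT1, KRT10, IVL, LOR, FLG, TP63, MKI67); the 5 largest rises and 5 largest falls among rows past the threshold with at least 10 CPM in the higher group and the same direction in all 3 replicate numbers; and in each list the 2 largest changes past the threshold with at least 5 CPM in the higher group and the largest change against the list's majority. It gave 78 genes, 75 of them called; 3 of these are not reported here. The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter, a filter of 5 CPM in 3 libraries, the replicate block, each library and each replicate number left out, a test against a doubling (glmTreat), camera with an estimated correlation and fry. After seeing the data 3 more were added: counts divided by 3, protein-coding rows only, and no mitochondrially encoded rows.

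The steps were tested on simulated counts for the same 22390 genes in 3 against 3 libraries. Of 100 genes changed 2-fold 56 were called and of 100 changed 4-fold 98, all in the right direction. Of 22161 unchanged genes 10 were called, and of 30 lists only the one lowered on purpose was called. The simulated genes varied independently, without replicate effects, and most were unchanged, unlike the real data. The simulation therefore does not test the preset correlation of the list test. Isoform and exon use was not analysed here. Genes on the Y chromosome and XIST are not reported.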

Results

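Messenger RNA was measured in primary human epidermal keratinocytes, the main cell type of the outer skin, grown in culture in 2 states. Progenitor cultures were kept in growth medium, and differentiated cultures were held at 100% confluence with 1.2 mM calcium for 96 hours, a standard way to start the program by which these cells build the upper layers of the epidermis. There were 3 libraries of each state. The summed counts per library lay between 195771996 and 197361666 in progenitors and between 190665543 and 192947181 in differentiated cells. Of the 47352 rows in the files, 26427 ± 371 had a count in progenitors and 28743 ± 650 in differentiated cells (SD, n = 3 each). Rank correlations of counts across genes within 1 library pair ran from 0.974 to 0.990 inside a group and from 0.880 to 0.899 between groups. The series is about alternative splicing, and its design compares mRNA isoforms between the 2 states; the files used here hold 1 count per gene, so isoform use itself was not analysed here, and what follows is gene expression, that of the splicing factors included. The labels do not state that the replicates came from separate donors, so p-values measure the spread between these samples.

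The first question was how far the transcriptome of the differentiated cells departed from that of the progenitors. The markers of the upper epidermis rose from near 0: KRT1 and KRT10, the keratins of the spinous layer, went from 1.45 ± 0.664 to 2400 ± 1270 CPM and from 9.24 ± 0.921 to 3250 ± 1390 CPM (counts scaled to the size of the library, SD, n = 3 each), which are log2 fold changes of 10.69 ± 0.66 and 8.46 ± 0.40 (SE). FLG, which encodes the precursor of filaggrin, rose 147-fold, and IVL, a cornified envelope protein, rose 25.4-fold. MKI67, the gene of the proliferation marker Ki-67, fell from 438 ± 74.4 to 0.181 ± 0.0495 CPM. The basal keratins stayed abundant: KRT5 stood at 19600 ± 1760 CPM in progenitors and 18100 ± 2050 in differentiated cells, with a log2 fold change of -0.11 ± 0.13 and an adjusted p of 0.498 by edgeR's quasi-likelihood test. That sign turned under other settings, to 0.06 with upper-quartile scaling. KRT14 had a log2 fold change of -0.24 ± 0.11 and an adjusted p of 0.103, which became 0.0403 with the replicate number as a block, and TP63, the transcription factor of epidermal stem cells, had -0.23 ± 0.17 and 0.282.

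**Figure D1:**
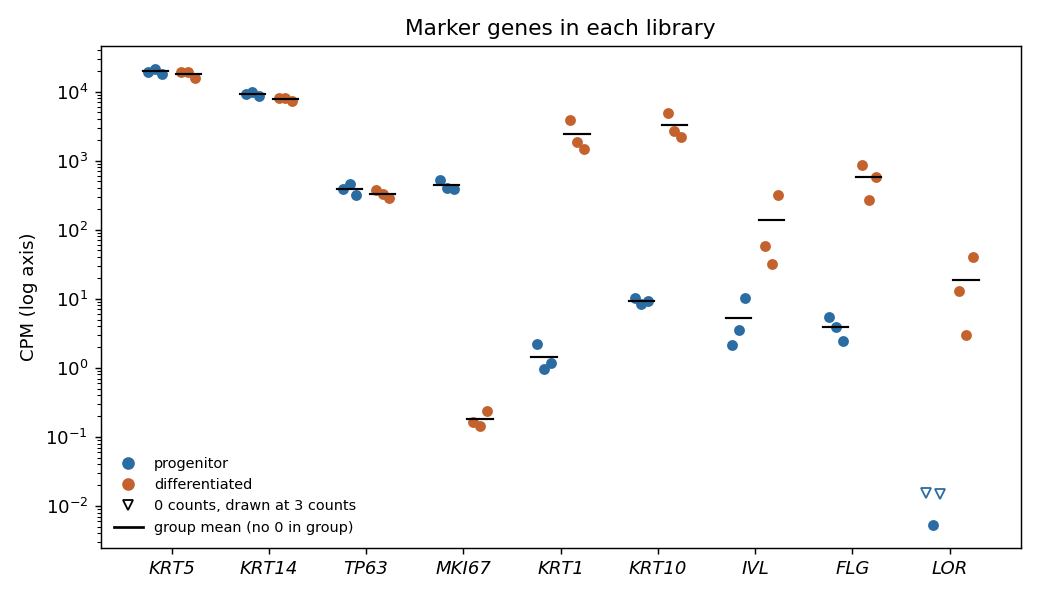
Counts per library size (CPM) of 9 marker genes on a log axis, 1 point per library, with progenitor libraries in blue and differentiated libraries in orange, bars at the group means, and open triangles for libraries with 0 counts drawn at the value of 3 counts. KRT5, KRT14 and TP63 overlap or lie close between the groups, MKI67 is lower in all 3 differentiated libraries, and KRT1, KRT10, IVL, FLG and LOR are higher in all 3.

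LOR, which encodes loricrin, the main protein of the cornified envelope, had 1 count in the 3 progenitor libraries together against 10776 in the differentiated ones, a ratio of 10800 with a 95% counting interval from 1940 to 427000. Its differentiated level was 18.6 ± 19.2 CPM (SD, n = 3), and its fitted log2 fold change of 12.95, which at such counts depends on the prior count, was 14.82 without progenitor replicate 2 and 11.71 without differentiated replicate 3. IVL was uneven as well, at 136 ± 157 CPM in differentiated cells. Its log2 fold change of 4.67 ± 1.10 was 3.08 without differentiated replicate 3 and 5.56 without progenitor replicate 3. Both libraries of replicate 3 had the highest IVL level of their group, 10.3 CPM in progenitors and 316 CPM in differentiated cells. By edgeR its adjusted p was 0.0103, or 0.000717 with the replicate block. Among rows with at least 10 CPM in the higher group, the largest rises beside LOR and KRT1 were those of ATP13A4, AADACL2 and PSAPL1. ATP13A4 had 1 progenitor count against 7951, a ratio of 7980 with an interval from 1430 to 315000, and a fitted log2 fold change of 12.49, or 14.35 without progenitor replicate 1. AADACL2 rose by 11.40 ± 1.11 on the log2 scale, or 12.04 without progenitor replicate 3, and PSAPL1 by 10.88 ± 1.57. Limma-voom, run without the replicate block, did not call PSAPL1. By edgeR the adjusted p of PSAPL1 was 0.00139, or 5.14e-05 with the replicate block. The largest falls at that level were in genes of the dividing cell. KIF18B, a mitotic kinesin, had 14549 counts in progenitors and 0 in differentiated cells, at least 1600-fold lower when each library at 0 is given 3 counts. SPC25, of the kinetochore, went from 7715 counts to 3, a ratio of 2560 with an interval from 876 to 12400, and a fitted log2 fold change of -11.15, or -14.33 without differentiated replicate 2. MKI67, DLGAP5 and NEK2 had log2 fold changes of -11.24 ± 0.29, -10.84 ± 0.31 and -10.57 ± 0.84; NEK2 had 9 differentiated counts in all, and its fitted change was -9.98 without differentiated replicate 1 and -15.22 without differentiated replicate 3.

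By edgeR's quasi-likelihood test at an adjusted p of 0.05, 12964 of 22390 tested rows changed (57.9%): 6620 were higher and 6344 lower in differentiated cells. Of these, 4725 at least doubled and 3423 were at least halved by the estimated fold change. Rows counted as protein-coding were those with a current RefSeq symbol of that type, so genes under an older symbol were left out. Among these 13363 rows, 3663 were higher and 4684 lower in this fit. When the same rows were scaled and fitted alone, 4083 were higher and 4153 lower. Called rows under 1 CPM on average were mostly higher (2256 higher and 810 lower, of 6856 tested). Called rows over 16 CPM were mostly lower (2121 higher and 3677 lower, of 8541 tested). When the fold change itself was tested against a doubling, 2970 rows were higher and 2145 lower, and a filter at 5 CPM left 4090 higher and 4094 lower of 12205 rows. Upper-quartile scaling moved the median log2 fold change of the tested rows from 0.05 to 0.22 and gave 7858 higher and 5242 lower.

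Gene lists fixed before the data were examined describe these changes by function, and each list gives the number of members that passed over all tested rows. For 21 of the 30 lists camera, which compares a list with all other genes at a preset correlation of 0.01, gave an adjusted p below 0.05, 8 of them higher and 13 lower. With the correlation estimated from these 6 libraries no list passed by camera, and 8 of 30 had an unadjusted p below 0.05. Fry, which asks whether members move on balance one way and makes no comparison with other genes, called 24. Every camera call below thus holds at the preset value and not with the estimate. For the basal and 3' end processing lists the estimate was -0.0142 and -0.00792, below the preset value. A higher correlation between genes therefore did not end those 2 calls. For the other called lists the estimate lay above the preset value, in some by little. It was 0.0183 for nonsense-mediated decay, 0.0274 for desmosomes and 0.0275 for cholesterol synthesis. Whether the correlation itself ended their calls was not tested. A few genes sit in more than 1 list, among them DSG1, DSC1, NOTCH3 and KLF4. The genes that the fixed rule gave are the markers, the largest changes and the leading members of each list; every other member named, such as those that complete a count of 5 or fewer, ESRP2, RBM24, NOVA1 and MFAP5, was chosen after its values were seen.

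**Figure D2:**
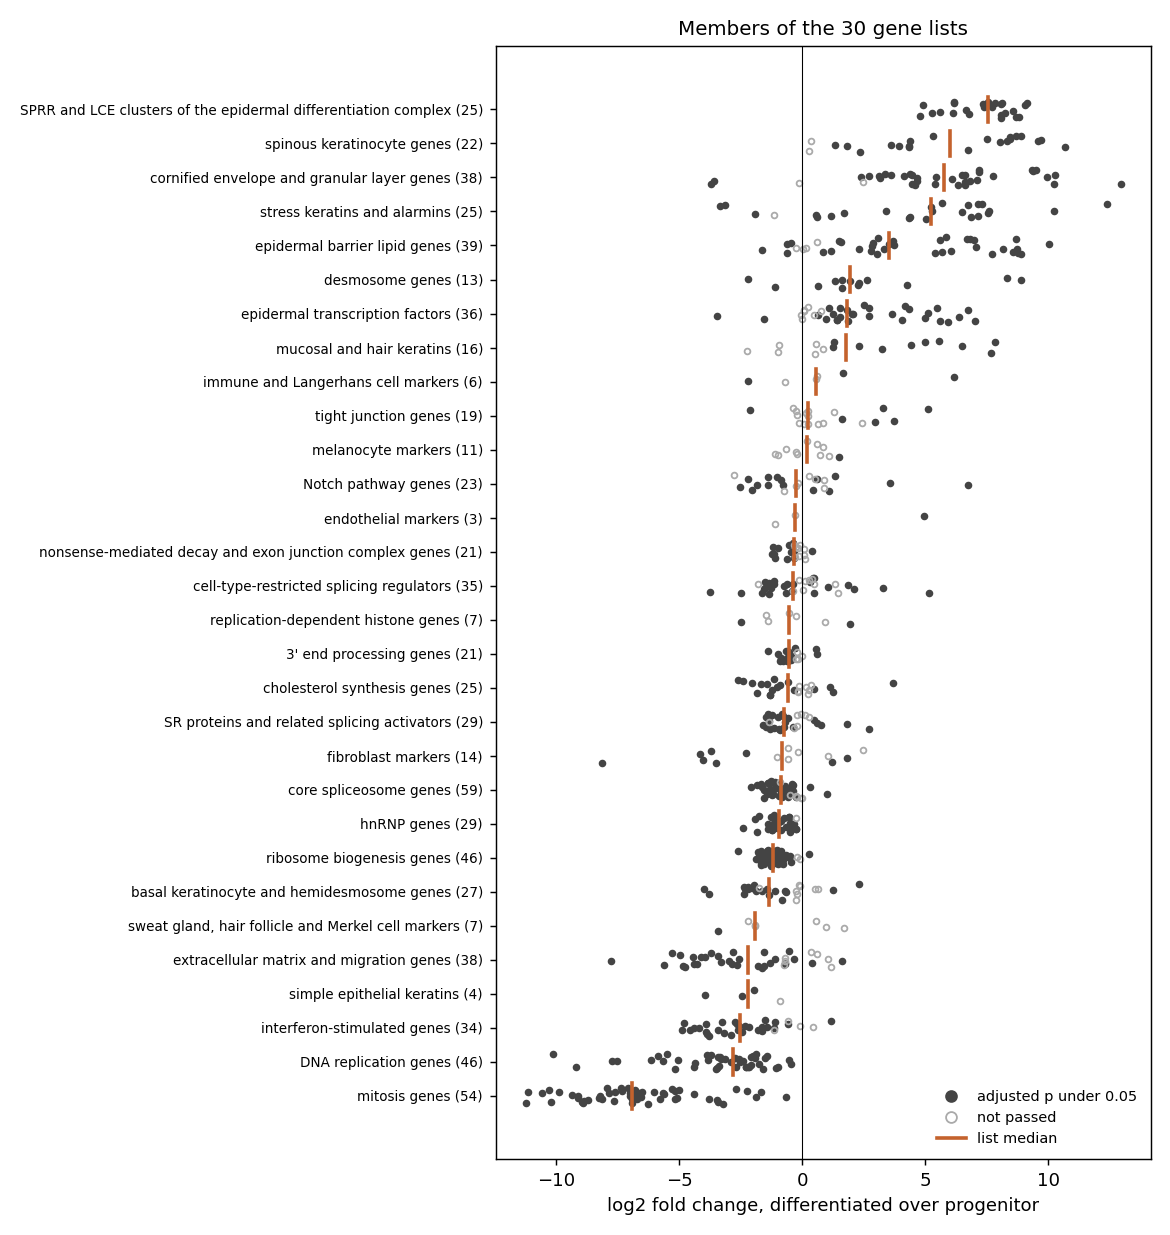
Log2 fold changes of the tested members of the 30 gene lists, differentiated over progenitor, 1 point per gene, with the number of tested members in brackets, dark points for members with an adjusted p under 0.05, open grey points for the rest and an orange bar at each list's median. The medians run from -6.91 for mitosis genes to 7.56 for the SPRR and LCE clusters.

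The cell division genes fell without exception. All 54 mitosis genes were lower, with a median log2 fold change of -6.91, and all 46 DNA replication genes, with a median of -2.82. RRM2, a subunit of ribonucleotide reductase, fell from 189 ± 18.7 to 0.169 ± 0.0344 CPM (SD, n = 3 each), and MCM10, a replication initiation factor, fell 583-fold. Camera gave an adjusted p of 3.87e-26 for the mitosis list and 3.33e-20 for the replication list, and these were adjusted p = 0.190 and 0.200 with an estimated correlation. Of 46 ribosome biogenesis genes 43 fell, with a median of -1.19; UTP20 fell 6.11-fold and EBNA1BP2 3.69-fold. POLR1C (-0.20) and NOB1 (-0.10) did not pass, and IMP3 alone was higher, by 0.26 ± 0.09 on the log2 scale with an adjusted p of 0.0498. IMP3 lost its call with the replicate block (adjusted p = 0.0551) and when any single library was left out (0.0668 to 0.161). The ribosome biogenesis list had a camera adjusted p of 4.22e-14, and adjusted p = 0.229 with an estimated correlation. Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, were all under 1 CPM: of 7 tested, HIST1H3D was higher, HIST1H4C lower and 5 did not pass, with a camera adjusted p of 0.619.

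The genes of the upper epidermal layers rose together. Among 22 spinous layer genes 20 rose and none fell, with a median log2 fold change of 6.02; KRTDAP, a secreted protein of the spinous layer, went from 1.52 ± 0.779 to 1270 ± 674 CPM (SD, n = 3 each), and ZFP36 (0.37) and S100A14 (0.30) did not pass, though S100A14 did with the replicate block (adjusted p = 0.0364). Of 38 cornified envelope and granular layer genes 34 rose, among them SLURP1 by 10.29 ± 0.59 on the log2 scale. PADI2 and PADI3, peptidylarginine deiminases, fell (log2 fold changes -3.59 and -3.70), while PADI1 (2.46) and BLMH (-0.13) did not pass. All 25 tested SPRR and LCE genes, small envelope proteins encoded in the epidermal differentiation complex, rose, with a median of 7.56. SPRR2E rose 531-fold. LCE2D rose by 9.13 ± 1.85 on the log2 scale. It stood at 8.55 without progenitor replicate 2, 10.08 without progenitor replicate 3 and 7.81 without differentiated replicate 3. Limma-voom, run without the replicate block, did not call it. By edgeR its adjusted p was 0.00559, or 5.92e-05 with the replicate block. Most of these genes were lowest in differentiated replicate 2: 14 of 22 spinous, 23 of 38 cornified and 18 of 25 SPRR and LCE genes. In that library the median deviation of SPRR and LCE genes from the group mean was -2.60 on the log2 scale. It was 0.69 and 2.02 in the other 2 libraries. Differentiated replicate 2 also had the highest share of mitochondrially encoded counts, 13.9% against 9.27% and 9.65%. Progenitor replicate 2 likewise had the highest share of its group, 10.4% against 8.46% and 9.40%, so this was not particular to the differentiated library. The camera adjusted p was 1.27e-09 for the spinous, 4.54e-07 for the cornified and 2.77e-04 for the SPRR and LCE list, and adjusted p = 0.116, 0.234 and 0.408 with an estimated correlation.

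Genes of the barrier lipid list mostly rose too, though not all of them encode lipid enzymes (ST14 encodes a protease). Of 39 barrier lipid genes 31 rose, or 32 adjusted over the list alone, with a median log2 fold change of 3.52. LIPM, an epidermal lipase, rose from 0.0402 ± 0.0611 to 43.8 ± 26.1 CPM, a log2 fold change of 10.04 ± 1.15 that was 12.86 without progenitor replicate 3, and DEGS2, which makes phytoceramides, rose 471-fold. In 33 of the 39 the lowest differentiated level was in replicate 2, the library with the highest mitochondrial share (median deviation -0.47 on the log2 scale). ELOVL6, CERS5, SPTLC2 and ST14 fell, ELOVL6 3.13-fold, and ELOVL1 (0.61), UGCG (0.04), SPTLC1 (0.18) and KDSR (-0.25) did not pass. Of 36 epidermal transcription factors 27 rose, among them ELF3 (132-fold). FOSL1, an AP-1 subunit, fell by 3.46 ± 0.42 on the log2 scale and stood at -4.06 without differentiated replicate 3, and VDR fell by 1.55. In the desmosome list 11 of 13 rose. DSC1 rose by 8.91 ± 0.95 on the log2 scale, or 7.99 without differentiated replicate 1, and DSG1 by 8.35 ± 0.60. DSG2 and PKP2, which are also common in simple epithelia, fell, with log2 fold changes of -1.10 and -2.19 ± 0.39; without differentiated replicate 3 PKP2 stood at -2.79. The camera adjusted p was 1.67e-06 for barrier lipids, 6.78e-07 for transcription factors and 4.01e-04 for desmosomes, and adjusted p = 0.301, 0.116 and 0.116 with an estimated correlation.

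Of 25 stress keratins and alarmins 21 rose, with a median log2 fold change of 5.24. S100P rose by 10.25 ± 0.73 on the log2 scale (9.65 without differentiated replicate 3) and LCN2, an iron-scavenging defence protein, rose 194-fold (a log2 fold change of 8.51 without progenitor replicate 3). S100A2, IL1A and IL8 fell, with log2 fold changes of -3.14, -1.93 and -3.34; IL8 lost its call without progenitor replicate 2 (adjusted p = 0.0547) or without differentiated replicate 1 (0.0515), and stood at -5.24 without differentiated replicate 3. IL1B (-1.15) did not pass, except with the replicate block (adjusted p = 0.0394). Camera gave the list an adjusted p of 1.57e-04, and adjusted p = 0.234 with an estimated correlation. In the tight junction list 13 of 19 members did not pass and the camera adjusted p was 0.216. CLDN1 rose 13.2-fold, OCLN 9.67-fold (18.5-fold without progenitor replicate 3), and CLDN4, TJP3 and CXADR also rose, while MPDZ fell 4.38-fold; with the replicate block 7 were higher and 2 lower.

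Keratins made up 4.04 ± 0.140% of counts in progenitors and 5.33 ± 0.308% in differentiated cells (SD, n = 3 each), a difference of 1.29 percentage points. All 3 differentiated libraries lay above all 3 progenitor libraries, and the exact two-sided permutation p of 0.1 is the smallest that 3 against 3 can give. Of 16 mucosal and hair keratins 10 rose and 6 did not pass; with the replicate block 2 of those 6, KRT31 and KRT75, were lower (adjusted p = 0.00732 and 0.0221). KRT78 rose by 7.82 ± 0.83 on the log2 scale (8.62 without progenitor replicate 3) and KRT23 by 7.68 ± 1.33 (8.85 without progenitor replicate 3, 6.34 without differentiated replicate 3). Of 4 simple epithelial keratins 3 fell: KRT8 (log2 fold change -2.44 ± 0.15), KRT18 (-1.96) and KRT7 (-3.93 ± 0.94), the last standing at -3.07 without progenitor replicate 3 and -4.92 without differentiated replicate 3; KRT19 (-0.90) did not pass. The mucosal list had a camera adjusted p of 0.0250, lost without progenitor replicate 2 (0.0614), and the simple keratin list 0.0429, lost without differentiated replicate 1 (0.0579); they were adjusted p = 0.290 and 0.301 with an estimated correlation, and the 5 CPM filter ended both (0.323 and 0.0779).

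Genes of the basal layer and of its contact with the matrix went the other way. Of 27 basal keratinocyte and hemidesmosome genes 17 fell, with a median log2 fold change of -1.33. NT5E, a cell surface nucleotidase, fell from 538 ± 60.5 to 39.6 ± 14.1 CPM (SD, n = 3 each). KRT15, a basal keratin, rose by 2.32 ± 0.49 on the log2 scale, and LAMA5 by 1.26; with the replicate block 4 were higher, DST and BCAM (adjusted p = 0.0459 and 0.0332) being added. Of 38 extracellular matrix and migration genes 29 fell, with a median of -2.18. THBS1, thrombospondin 1, fell from 4560 ± 861 to 21.1 ± 14.1 CPM, a log2 fold change of -7.76 ± 0.59 that was -8.46 without differentiated replicate 3. FN1, fibronectin, had a log2 fold change of -5.62 ± 1.14, or -4.94 without progenitor replicate 1, and LOX and AMOTL2 rose. Camera gave adjusted p values of 3.13e-05 for the basal and 1.19e-06 for the matrix list, and adjusted p = 0.116 and 0.190 with an estimated correlation. Fibroblast markers overlapped this trend in part, with 6 of 14 lower and 2 higher and a camera adjusted p of 0.303. THY1 (log2 fold change -8.14 ± 0.78, or -9.13 without differentiated replicate 3) and FBN1 (-3.48 ± 0.42) fell, both from under 10 CPM, and MFAP5, the most abundant of these markers, went from 166 ± 36.2 to 33.9 ± 13 CPM (SD, n = 3 each). COL1A1 and DCN rose by 1.20 and 1.84 ± 0.31, and with the replicate block so did PDGFRA and S100A4 (adjusted p = 0.0476 and 0.00426).

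The splicing machinery, the subject of the series, was mostly lower in differentiated cells. Of 59 core spliceosome genes 51 fell, with a median log2 fold change of -0.87; SNRNP25 fell 4.19-fold and SNRPA, of the U1 particle, 3.52-fold. SYF2 and SLU7 rose, by 1.03 ± 0.12 and 0.32. Of 29 hnRNP genes, which encode abundant RNA-binding proteins that often repress exons, 28 fell, with a median of -0.93, and HNRNPH2 (-0.24) did not pass. HNRNPD went from 309 ± 18.0 to 57.8 ± 4.82 CPM and HNRNPM from 255 ± 15.3 to 68.0 ± 6.47 CPM (SD, n = 3 each). Of 29 SR proteins and related activators 17 fell, or 18 adjusted over the list alone, with a median of -0.74, and 7 did not pass. The 5 that rose were CLK1 (6.56-fold), CLK4 (3.53-fold), PNISR, SRSF5 and SRSF8; CLK1 and CLK4 are kinases that phosphorylate SR proteins. With upper-quartile scaling, which shifts all genes nearly alike, the 3 medians were -0.70, -0.76 and -0.57. The camera adjusted p was 5.14e-14 for the spliceosome, 1.01e-10 for hnRNP and 0.00171 for SR genes, and adjusted p = 0.116, 0.116 and 0.234 with an estimated correlation.

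**Figure D3:**
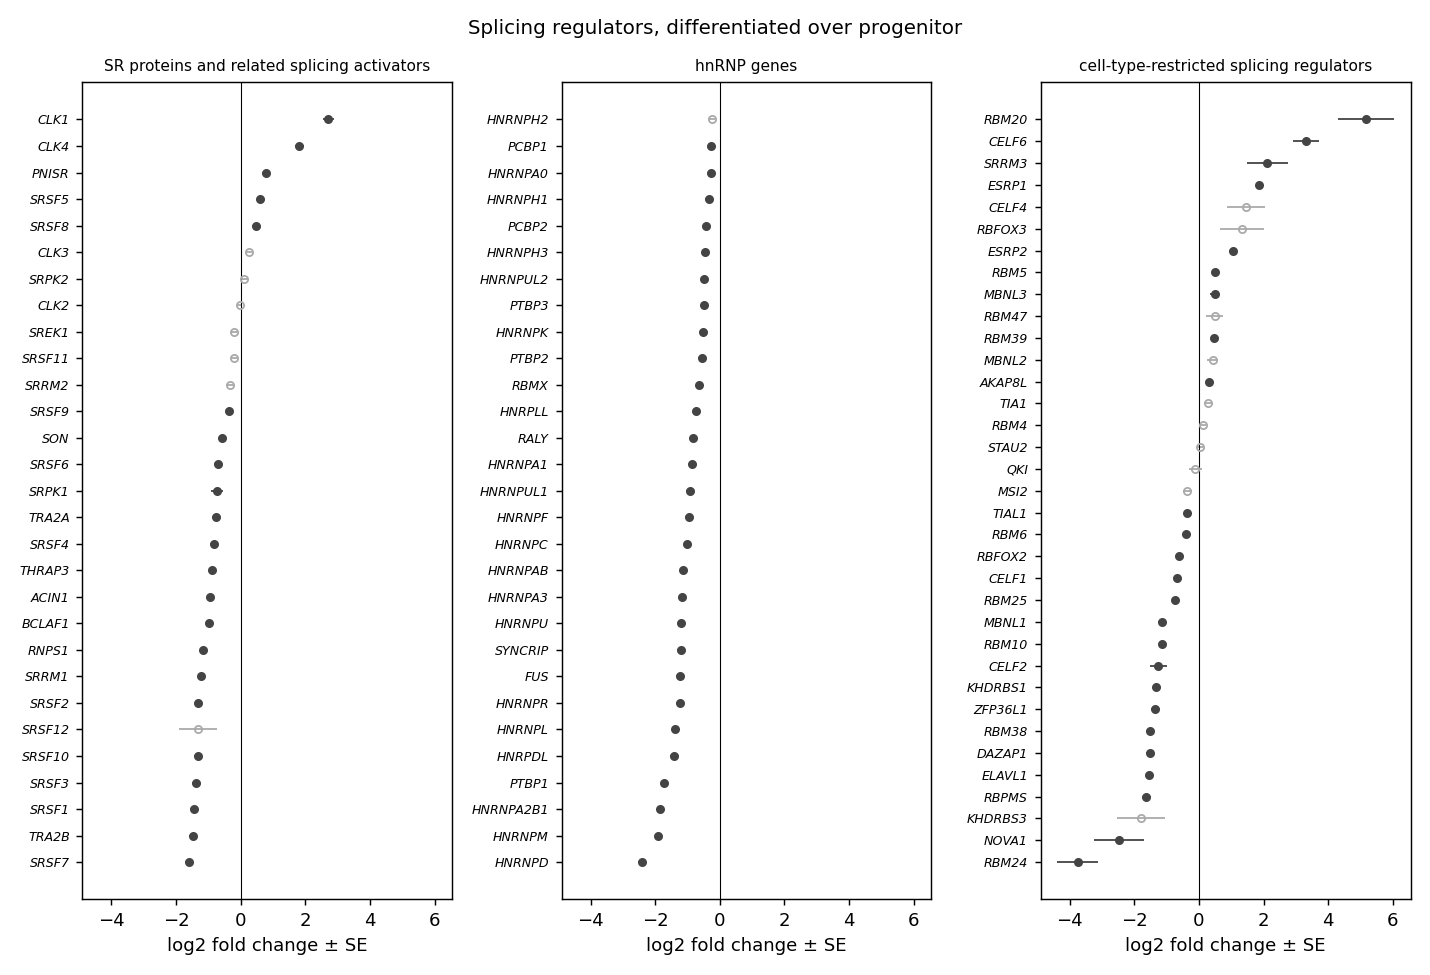
Log2 fold change of each tested gene in 3 lists of splicing regulators, differentiated over progenitor, with bars of 1 standard error, dark points for an adjusted p under 0.05 and open grey points for the rest. Most hnRNP and SR genes lie left of 0, CLK1 and CLK4 lie to the right, and the cell-type-restricted regulators spread to both sides from RBM24 to RBM20.

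Cell-type-restricted splicing regulators went both ways: of 35 tested, 9 rose, 16 fell and 10 did not pass, with a camera adjusted p of 0.216. ESRP1, the epithelial splicing regulator, rose from 147 ± 3.96 to 532 ± 27.3 CPM (SD, n = 3 each), a log2 fold change of 1.85 ± 0.08, and ESRP2 rose by 1.05. RBPMS fell 3.09-fold, and RBM20, RBM24 and NOVA1 changed at levels under 1 CPM. Of 21 genes of nonsense-mediated decay and the exon junction complex 11 fell and 9 did not pass; MAGOH and its copy MAGOHB fell 2.27-fold and 2.36-fold, and PNRC2 alone rose, by 0.41 ± 0.09 on the log2 scale. Of 21 genes of 3' end processing 15 fell, CSTF2 2.59-fold and CPSF3 1.96-fold, while PABPC1 and PCF11 rose by 0.59 ± 0.10 and 0.55. The camera adjusted p was 0.00455 for the decay list, lost with the 5 CPM filter (0.154), and 4.41e-04 for 3' end processing; they were adjusted p = 0.181 and 0.116 with an estimated correlation.

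Interferon-stimulated genes fell: of 34, 29 were lower (30 adjusted over the list alone), 4 did not pass (OASL, RSAD2, SAMD9 and BST2, the last with an adjusted p of 0.0118 with the replicate block) and ISG20 was higher, by 1.19 ± 0.28 on the log2 scale. MX2 fell from 29 ± 15 to 0.970 ± 0.476 CPM and IFIT3 from 64.1 ± 31.0 to 2.32 ± 0.148 CPM (SD, n = 3 each). The median was -2.51, with a camera adjusted p of 3.8e-10, and adjusted p = 0.200 with an estimated correlation. Of 25 cholesterol synthesis genes 14 fell and 7 did not pass, while TM7SF2 (12.9-fold), PMVK, SC5DL and SREBF2 rose; the camera adjusted p of 0.0250 was lost with the 5 CPM filter (0.152), and was adjusted p = 0.229 with an estimated correlation. Notch pathway genes went both ways, with 6 higher, 9 lower and 8 not passed of 23 and a camera adjusted p of 0.408. NOTCH3 rose from 2.07 ± 1.13 to 219 ± 26.1 CPM and MAML3 11.9-fold.

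No list of markers of other cells that a skin culture could hold passed by camera, and single markers did change. Of 11 melanocyte markers GPR143 rose and 10 did not pass (camera adjusted p = 0.619); PMEL was also higher with the replicate block (adjusted p = 0.0212). Of 6 immune and Langerhans cell markers CD14 and FCER1G rose, by 6.16 and 1.67 on the log2 scale, CD74 fell and 3 did not pass (0.453); fry gave an adjusted p of 0.000657. Of 3 endothelial markers, all under 1 CPM on average, VWF rose by 4.94 on the log2 scale and 2 did not pass. The median was -0.28 although the camera direction was up (0.922). Among 7 markers of sweat gland, hair follicle and Merkel cells SOX9 fell, with a log2 fold change of -3.43 ± 0.79 (-4.57 without differentiated replicate 3), and 6 did not pass (0.889), with a list median of -1.90; with the replicate block 2 were higher (SOX2 and FOXC1) and 3 lower (SOX9, LGR6 and LHX2).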

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

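Division of counts by 3, protein-coding rows only and removal of mitochondrially encoded rows were chosen after seeing the data. No row was called in opposite directions under any other tool, scaling, filter or the replicate block. Counts higher, lower, doubled and halved were 4090, 4094, 1980 and 1737 with the 5 CPM filter and 4083, 4153, 2507 and 2062 on protein-coding rows, which test fewer rows; glmTreat, which tests the size itself, gave 2970 doubled and 2145 halved. Leaving out libraries gave 4495 to 6405, 4417 to 6329, 3642 to 4634 and 2855 to 3575, the lowest without replicate 1, where each group has 2 libraries. The replicate block gave 7132 higher and 6803 lower; it called KRT14, lost IMP3 and changed no other call of a list or of a gene the naming rule gave, while it moved the number of called members in several lists; those it moved by over 1.5 times stand beside their lists. For KRT5 the log2 fold change turned to 0.06 with upper-quartile scaling and with the 5 CPM filter (0.064) and to 0.00071 on protein-coding rows. Upper-quartile scaling also moved the median of all tested rows up, from 0.05 to 0.22, so that turn was not particular to KRT5. For the filter and the protein-coding rows the cause was not tested. Of 75 called named genes limma-voom lost 3 (PSAPL1, LCE2D and IMP3), and leaving out replicate 1 lost 6 (LCE2D, OCLN, IL8, IMP3, KRT7 and SOX9), replicate 2 lost 3 (IL8, IMP3 and PNRC2, the last at an adjusted p of 0.0532) and replicate 3 IMP3. The keratin difference was 1.53 points without mitochondrially encoded genes and 1.09 to 1.44 with libraries left out.

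All 21 list calls were lost with an estimated correlation: adjusted p was 0.116 for basal, spinous, transcription factor, desmosome, hnRNP, spliceosome and 3' end processing lists, 0.181 for nonsense-mediated decay, 0.190 for mitosis and matrix, 0.200 for replication and interferon, 0.229 for ribosome biogenesis and cholesterol, 0.234 for cornified, stress and SR, 0.290 for mucosal keratins, 0.301 for barrier lipids and simple keratins and 0.408 for SPRR and LCE. The 5 CPM filter also ended nonsense-mediated decay (0.154), cholesterol (0.152), simple keratins (0.0779) and mucosal keratins (0.323), and protein-coding rows ended nonsense-mediated decay (0.0639), cholesterol (0.0505) and simple keratins (0.0639); counts divided by 3 ended simple keratins (0.0544). Leaving out libraries gave 0.0167 to 0.0579 for simple and 0.00884 to 0.0614 for mucosal keratins. Fry called cell-type-restricted splicing regulators (0.000122), Notch (0.000769) and immune markers (0.000657). The histone list passed with no filter (0.0408) and turned direction with counts divided by 3 (0.959). Direction also turned for uncalled lists: with no filter for endothelial (0.862) and sweat gland, hair follicle and Merkel cell markers (0.967), and in some settings that leave out libraries for melanocyte, endothelial and sweat gland, hair follicle and Merkel cell markers, whose adjusted p over all such settings, turned or not, ran from 0.255 to 0.989, 0.769 to 0.995 and 0.586 to 0.996. The cause of these was not tested.

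The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05; 1 split, the real one, gave as many rows. It called 6620 rows higher, 6344 lower, 4725 doubled and 3423 halved by edgeR, and the highest of the others was 0 for each (22 to 394 rows at an unadjusted p below 0.05, against 14040). For lists the real split called 21 and the highest other 20. The 3 other splits that part all 3 replicate pairs called 17 to 20 lists, and the 6 that part 1 pair 11 to 20. Camera at the preset correlation thus called lists in every split. In every split but the real one, each group mixes libraries of both states. Part of the difference between states then stays between the groups, and the rest widens the spread within them. These splits therefore cannot tell whether their list calls are false, or whether 0 called rows reflects few false row calls.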

Other observations

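Several actin, tubulin, filamin and myosin genes were picked after their values were seen and are not a tested group; each named here was lower in differentiated cells by edgeR's test. ACTB fell from 8010 ± 953 to 874 ± 103 CPM (SD, n = 3 each), ACTG1 3.72-fold, TUBA1B 18.5-fold, TUBB 7.02-fold, FLNA 6.53-fold and MYH9 5.07-fold. ACTB is a common reference gene for relative quantification. Among small nucleolar and Cajal body RNA rows 84 of 181 fell and 13 rose, with a median log2 fold change of -0.87. Such rows took only 0.0121 ± 0.00146% of counts in progenitors and 0.0091 ± 0.000883% in differentiated cells. As poly(A) RNA was sequenced, they may hold reads of other transcripts, so a fall of the small RNAs themselves was not shown. Rows named XLOC, transcripts without a gene symbol, took 0.205 ± 0.00277% of counts in progenitors and 0.443 ± 0.0647% in differentiated cells, and 570 of 1350 tested rose and 112 fell.

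In the patterns weighed next, the tests of gene length, GC content and expression level were set before their results were seen and the others after; each pattern was chosen after its values were seen.

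The core spliceosome, hnRNP and SR lists, 117 genes together, fell by a median of 0.86 on the log2 scale. In 10000 random lists matched on mean expression, transcript length and GC content, each gene drawn from its 100 nearest neighbours, the median ran from -0.41 to -0.07 (central 95%), and the observed one lay at percentile 0, so these properties do not account for the fall. The fall remained under the other scalings tried: the median nearest 0 under RLE and upper-quartile scaling was -0.68. All these scalings rest on the bulk of the genes, so they cannot exclude a shift in total mRNA, which would move this median. Set against the median of all tested rows, the members' median was -0.90, a difference that 1 factor per library cannot make. A lower demand for splicing factors in cells that stopped dividing is a candidate explanation and was not tested, because division and differentiation changed together.

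Cytoplasmic ribosomal protein genes rose while ribosome biogenesis genes fell. Of 79 ribosomal protein genes 75 rose and 4, RPL39L, RPL22L1, RPL26L1 and RPL7L1, fell (all paralogs of a ribosomal protein gene), with a median of 0.96, and their share of counts went from 3.55 ± 0.151% to 6.84 ± 0.336% (SD, n = 3 each). EEF1A1, a translation factor gene, rose 2.47-fold. The ribosomal protein median lay at percentile 100 of the matched lists (central 95% from -0.44 to 0.07). The 2 sets' medians differed by at least 2.15 on the log2 scale under TMM, RLE and upper-quartile scaling. Because 1 factor per library shifts both sets alike, it cannot make this gap. For the same reason the like gap under all 3 scalings adds no further support. A change in transcript stability or in poly(A) tail length, which poly(A) selection could read as abundance, may also contribute and was not tested.

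Interferon-stimulated genes together fell from 2346 ± 352 to 462 ± 78.2 CPM (SD, n = 3 each). A single library does not explain this, as 30 of 34 members were lower in all 3 replicate numbers and the list stayed called without any library at the preset correlation (largest adjusted p 1.23e-09; adjusted p = 0.200 with an estimated correlation and all libraries). Immune cells in the progenitor cultures are argued against by PTPRC and TYROBP, 2 of 14 fixed immune markers, picked after their values were seen, which reached at most 0.016 CPM there; of the other markers CD74 stood at 3.45 ± 1.03 CPM in progenitors, and CD68, the most abundant, at 19.9 ± 7.88 there and 29.3 ± 8.08 CPM in differentiated cells (adjusted p = 0.174, or 0.00658 with the replicate block). IFNK, the interferon of keratinocytes, fell with them, with a log2 fold change of -2.31, from 61.4 ± 22.0 to 12.4 ± 6.74 CPM (adjusted p = 0.00845), as did the receptor genes IFNAR2, 3.54-fold, and IFNAR1, 1.40-fold, while IFNGR1 rose 2.33-fold; of the other ligands IFNE stood at 0.825 ± 0.456 and 0.883 ± 0.0608 CPM (adjusted p = 0.851) and 19 rows had at most 12 counts in any library. A lower IFNK signal is a candidate cause that cannot be told apart from other effects of differentiation, since both follow the groups.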
